A study of Mus musculus with 9 samples.

How the data were processed

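Kidney RNA from 9 libraries was sequenced after TRIzol extraction and library preparation with the VAHTS Universal V6 kit, per the labels' protocols. The authors deposited 1 table of FPKM values for 26139 gene symbols in 9 libraries. The submitters' processing notes name fastp, HISAT2, HTSeq, DESeq2 and R 3.2.0 and the mouse build GRCm39, without roles. The gene annotation, the strand setting of the counting and the mapping parameters are not given in the sources used here, so a gene and an overlapping antisense gene cannot be told apart. Columns were matched to samples through the library names in the labels. Of the symbols, 24955 matched GENCODE M21 or RefSeq names and 1184 did not; no coordinates were used.

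FPKM divides reads by gene length and by the library total, so a few abundant genes can shift all others. The low FPKM values moved in steps, which gave the number of whole reads per gene within a tolerance of 0.03 reads for 26139 genes. For genes without reads or seen in 1 library this holds by construction. For genes seen in few libraries a match can easily arise by chance, since many multipliers were tried. Recovered totals of 30564947 to 38161564 reads per library were checked against the step sizes, and the largest difference from them was -0.0108%. No columns were identical, and replicate pairs differed by 17.7 to 189 in chi-square per gene, far beyond sampling noise.

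The main test was limma 3.58.1 in R 4.3.3 (linear model over all 9 libraries, empirical Bayes with a mean-variance trend) on log2(FPKM + 1), a pseudocount of 1. Genes with FPKM of at least 1 in at least 3 libraries were tested, 11617 in all, with Benjamini-Hochberg adjustment per comparison and a threshold of 0.05. Of 40 gene lists of kidney and immune cell types, stress, injury, metabolism and carried-over tissues, 32 had at least 5 tested genes. They were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, and adjusted over lists. By fry's directional test, which does not compare a list with other genes, 5, 5 and 0 lists passed in IgAN against WT, GQYS against IgAN and GQYS against WT. The tests, the lists and the alternatives other than 3 named here as added were fixed before the data were examined.

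The named genes were, per comparison, the 10 largest rises and 10 largest falls past the threshold with non-overlapping FPKM ranges, filled to 10 by the smallest unadjusted p among genes with non-overlapping ranges. Predicted and clone-named genes were counted but not named. Itgam, up to 4 members with the smallest p of each list described, and the 10 genes with the smallest larger p of the 2 comparisons for the reversal were added, and 1 gene so selected is left out. Genes used to describe single libraries (Egr1, Hspa1a, Havcr1, Cfd, Upk1a) and the clock, globin and neutrophil genes of the closing section were chosen after their values were seen.

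The model was tested on simulated data of 11617 genes. For IgAN against WT it recovered 14.9% of genes changed 1.5-fold, 62.7% at 2-fold and 90.9% at 4-fold, and 4.27% of its calls were false. For GQYS against IgAN it recovered 19.4%, 55.2% and 95.5%. The simulated noise was independent across genes and libraries, without structure shared within libraries, so these rates may not hold for the real data. Alternatives covered the pseudocount, the filter, the scaling, a replicate block, the samples in the fit, library quality weights, the prior and each library left out. Voom on the recovered reads, a fit without WT and IgAN replicate 1, and the mitochondrial share as a covariate were added after seeing the data, as was the count among the genes with the smallest p of each simulated draw for the reversal. A correlation was taken as unmoved within 0.126, its jackknife standard error over 9 leave-one-out fits, a rule adopted after the alternatives had been computed. Python 3.11.15 with matplotlib 3.10.9 drew the figures.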

Results

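Bulk RNA sequencing was carried out on mouse kidneys from 3 groups with 3 libraries each. The WT group consisted of C57/BL6 mice that received saline by gavage. The IgAN group carried human CD89, an Fc receptor for IgA, knocked in at Itgam, the gene of the myeloid integrin CD11b, and also received saline. The GQYS group carried the same knock-in and received Gui-qi-yi-shen granules, a Chinese herbal preparation, by daily gavage for 5 months. The series concerns the effect of these granules in IgA nephropathy, a glomerular disease with IgA deposits. Each library held between 30564947 and 38161564 reads assigned to genes, as recovered from the steps of the deposited FPKM values. Nothing in the labels states that the 3 libraries of a group came from separate animals, so p-values measure the spread between these libraries, which can be partly technical.

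Itgam, the knock-in locus, was examined first. It was low in all groups, at 0.495 ± 0.197 FPKM in WT, 0.289 ± 0.132 in IgAN and 0.0848 ± 0.0574 in GQYS (SD, n = 3 each). The 2-sided exact permutation p was 0.3 for IgAN against WT and 0.1 for both comparisons with GQYS, and 0.1 is the smallest p that 3 against 3 libraries allow. The limma fit on 23797 genes without a filter gave adjusted p of 0.620, 0.519 and 0.714 for IgAN against WT, GQYS against IgAN and GQYS against WT. The deposited FPKM values held 0 rows under the names FCAR or CD89 of the human gene, so the transgene itself does not check the labels.

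The libraries sorted only partly by group. The first principal component held 41.9% of the variance and set WT replicate 1 at -28.1 and IgAN replicate 1 at -23.8 apart from the other 7 libraries. The genes with the largest weights on it included Egr1, an immediate-early gene at 71.0 FPKM in WT replicate 1, Hspa1a, a heat shock gene with a near-identical copy that could share its reads, and Havcr1, the tubular injury marker KIM-1. The second component held 22.1% of the variance and placed the 3 IgAN libraries between 10.5 and 19.1 and the other 6 at or below -1.09. Mitochondrial genes took 18.6% of the reads in WT replicate 1 and between 7.81% and 13.3% in the others. WT replicate 3 carried fat and urothelial markers, with Cfd at 11.4 FPKM and Upk1a at 4.70 FPKM. Mean Euclidean distances over log2(FPKM + 1) of the tested genes were 36.6 between groups and 33.7 within groups. The difference was 2.95, and its one-sided exact permutation p over 280 splits was 0.1.

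**Figure D1:**
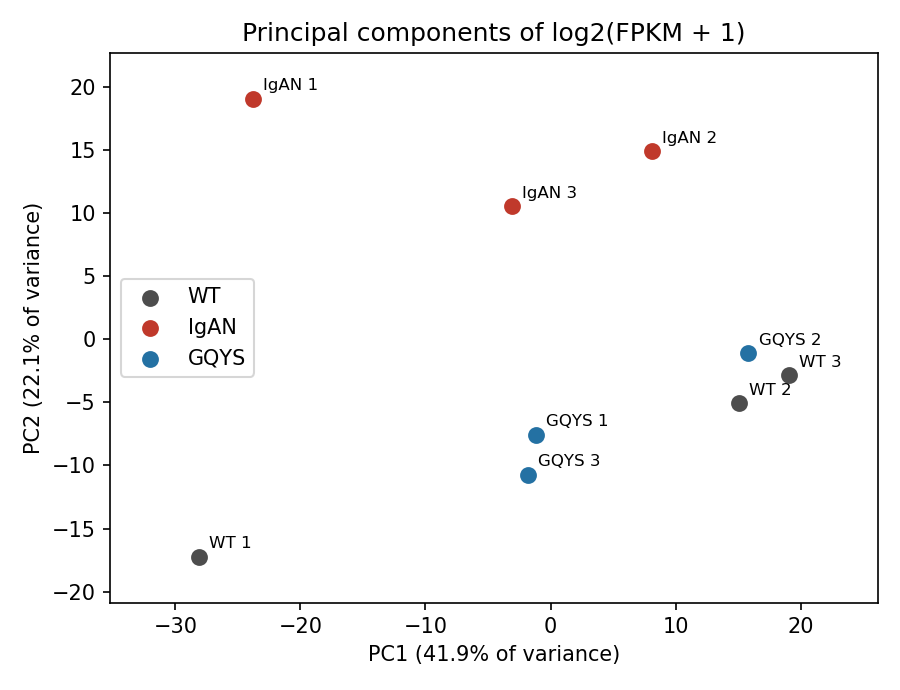
Principal component scores of the 9 libraries from log2(FPKM + 1) of the tested genes, with the first component (41.9% of variance) on the x axis, the second (22.1%) on the y axis and 1 point per library coloured by group. WT 1 and IgAN 1 lie at the left, and the 3 IgAN libraries lie at the top.

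The comparison of IgAN with WT asked how kidneys of knock-in mice differed from those of wild-type mice. S100a9 and S100a8, which encode the subunits of calprotectin, were at 15.6 ± 1.80 and 11.3 ± 2.08 FPKM in IgAN against 1.37 ± 0.603 and 0.923 ± 0.751 in WT (SD, n = 3; limma adjusted p = 0.000338 and 0.00312). Their log2 changes were 2.84 and 2.74, on a log2(FPKM + 1) scale that understates the change of low genes. Retnlg, a neutrophil-expressed resistin-like gene, stood at 2.50 ± 0.260 against 0.0532 ± 0.0921 FPKM. Other large rises were those of Zbtb16, a glucocorticoid-inducible transcription factor (5.25 ± 1.29 against 0.352 ± 0.0851 FPKM), Socs3, a feedback inhibitor of cytokine signalling (6.13 ± 2.24 against 0.697 ± 0.252), and Cebpd, an acute-phase transcription factor (log2 change 1.62). Depp1 and Angptl4, both known to respond to fasting, rose by 2.70 and 1.87 on the log2 scale. The calls of Cebpd and Angptl4 ended without WT replicate 2 (adjusted p = 0.0665 and 0.0573), that of Cebpd also without WT replicate 3 (0.0570) and that of Angptl4 also without IgAN replicate 3 (0.0752). Serpina3g rose by 2.03, but it has near-identical paralogs that could share its reads. In all, 41 of 11617 tested genes passed limma at an adjusted p of 0.05, 35 higher and 6 lower in IgAN. All 41 had FPKM ranges that did not overlap, as did 14.0% of all tested genes, where chance gives 10%. The 10 that passed under every alternative that tested them were S100a9, S100a8, Retnlg, Zbtb16, Socs3, Depp1, Serpina3g, Csf1, Casp4 and Herpud1.

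The 6 genes that fell were Tcf21, a transcription factor of podocytes and stromal cells (7.78 ± 1.61 against 21.1 ± 3.33 FPKM, adjusted p = 0.0115), Id3, Hpgd, which degrades prostaglandins, Nap1l5, Adamts5 and Ccdc68. Their log2 changes lay between -1.33 and -0.73. Each of these 6 calls ended without at least 1 library: adjusted p rose to 0.0547, 0.0694 and 0.111 for Tcf21, Hpgd and Adamts5 without WT replicate 2, and to 0.139, 0.161 and 0.178 for Id3, Nap1l5 and Ccdc68 without IgAN replicate 3. Pde9a, Pacc1, Ogn and Fpgs were the next lower genes and did not pass the threshold, with adjusted p between 0.0534 and 0.0755.

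Of the 18 tested genes of the inflammatory cytokine and NF-kB list, 4 rose over all genes tested and 12 adjusted over the list alone. The 4 were Ccl2, a monocyte chemoattractant (8.27 ± 0.528 against 1.53 ± 1.23 FPKM), Csf1, a macrophage growth factor (7.12 ± 0.590 against 2.53 ± 0.145), and the adhesion molecules Vcam1 (log2 change 1.12) and Icam1 (1.13). Without IgAN replicate 3 the calls of Ccl2, Icam1 and Vcam1 ended (adjusted p = 0.137, 0.102 and 0.0608). That of Icam1 also ended without WT replicate 2 and IgAN replicate 1 in turn (0.0665 and 0.0662), and that of Ccl2 held only without WT replicates 1 and 3 in turn. The camera test of this list gave an adjusted p of 2.86e-14, and an adjusted p of 0.144 with an estimated correlation. Of 19 endoplasmic reticulum stress genes, 2 rose over all genes tested, Herpud1 (log2 change 1.31) and Chac1 (0.84, a call that ended without 5 of the libraries in turn, with an adjusted p of 0.114 without IgAN replicate 3), and 13 adjusted over the list alone (camera adjusted p = 9.22e-16, adjusted p = 0.110 with an estimated correlation). None of the 17 heat shock genes passed over all genes tested and 12 did adjusted over the list alone, among them Hsp90ab1 at 806 ± 55.1 against 508 ± 61.6 FPKM (camera adjusted p = 9.49e-15, adjusted p = 0.144 with an estimated correlation). Of 17 glucocorticoid response genes, Zbtb16 and Angptl4 rose over all genes tested and 11 did adjusted over the list alone (camera adjusted p = 4.52e-10, adjusted p = 0.122 with an estimated correlation).

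The tubular injury list had 1 member past the threshold over all genes tested, Vcam1, though not without IgAN replicate 3 (0.0608), and 11 of 21 adjusted over the list alone (camera adjusted p = 1.09e-11, adjusted p = 0.229 with an estimated correlation). Havcr1 was at 43.8 FPKM in IgAN replicate 1 but at 1.33 and 1.79 in the other IgAN libraries. No gene of the extracellular matrix list passed over all genes tested and 15 of 28 did adjusted over the list alone, including Fn1, fibronectin, at 4.46 ± 0.826 against 2.67 ± 0.298 FPKM (camera adjusted p = 6.60e-10, adjusted p = 0.341 with an estimated correlation). IgAN replicate 1 carried much of both rises: without it the median log2 change of the matrix list went from 0.55 to 0.34 and that of the injury list from 0.74 to 0.48, with both calls kept. Of 24 immediate-early genes, Socs3, Maff and Klf6 rose, and 7 did adjusted over the list alone (camera adjusted p = 0.00269, adjusted p = 0.640 with an estimated correlation). The calls of Maff and Klf6 ended without 3 and 8 of the libraries in turn (adjusted p = 0.0947 and 0.111 without WT replicate 2), and that of Socs3 held. WT replicate 1 had the highest level of this list among the 9 libraries, and without it the median log2 change was 0.53 instead of 0.08, whereas without WT replicates 2 and 3 in turn it was 0.05 and -0.0017 and the call ended (adjusted p = 0.226 and 0.377). Without IgAN replicates 2 and 3 in turn it was 0.18 and 0.15. Angptl4 was the 1 member past the threshold among 36 genes of fatty acid oxidation and PPAR-alpha targets (camera adjusted p = 0.000770, adjusted p = 0.602 with an estimated correlation). The 13 mitochondrially encoded genes had a median log2 change of -0.32 and none passed (camera adjusted p = 0.00332, adjusted p = 0.640 with an estimated correlation), and WT replicate 1 had the highest mitochondrial share; without that library the list did not pass, its median was -0.02 and the direction of camera turned. The mesangial and fibroblast, interferon, glycolysis and ribosomal protein lists passed upward with camera adjusted p of 0.0119, 0.0232, 0.00269 and 0.0231, none of which held with an estimated correlation (adjusted p = 0.144, 0.640, 0.602 and 0.819). Without WT replicate 1 the fatty acid oxidation, glycolysis and interferon calls ended (adjusted p = 0.0602, 0.131 and 0.0520), and without WT replicate 3 the mesangial, interferon and ribosomal protein calls did (0.0618, 0.446 and 0.766). The ribosomal protein call also ended without WT replicate 2 (0.629), the interferon and ribosomal protein calls without IgAN replicate 1 (0.196 and 0.832), the mitochondrial call without IgAN replicate 2 (0.239) and the mesangial call without IgAN replicate 3 (0.0929). Thus 13 of 32 lists passed camera with the preset correlation of 0.01 and 0 with an estimated one. By fry's directional test 5 lists passed: inflammatory, endoplasmic reticulum stress, heat shock, glucocorticoid and mesangial (adjusted p = 0.00880, 0.00639, 0.0195, 0.00880 and 0.00639). That test does not compare a list with other genes and was not repeated without single libraries. The count of genes fell to 14 without WT replicate 2 and 15 without IgAN replicate 3, and rose to 65 without WT replicate 1 and to 58 without WT and IgAN replicate 1 together. It was 22 without WT replicate 3, 25 without IgAN replicate 1, 25 without GQYS replicate 2, 24 without GQYS replicate 3, 655 with library quality weights and 815 with the mitochondrial share as a covariate.

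The comparison of GQYS with IgAN asked how kidneys of knock-in mice that received the granules differed from those on saline. S100a9 was at 1.22 ± 0.304 FPKM in GQYS against 15.6 ± 1.80 in IgAN (SD, n = 3; limma log2 change -2.91, adjusted p = 0.000269). S100a8, Ccl2, Serpina3g, Zbtb16, Socs3, Retnlg and Cebpd fell by between 1.72 and 2.31 on that scale. Csf1 fell to 2.15 ± 0.340 FPKM, and Casp4, an inflammatory caspase, changed by -1.20. The rising genes were Tcf21 (18.4 ± 2.52 against 7.78 ± 1.61 FPKM), Igfbp3, an insulin-like growth factor binding protein (70.0 ± 4.17 against 35.6 ± 8.44), Nap1l5 and Pde9a, a cGMP phosphodiesterase. Without GQYS replicate 3 these 4 calls ended (adjusted p = 0.2, 0.293, 0.281 and 0.197), as did those of S100a8, Herpud1 and Cebpd (0.0841 each), Ccl2 (0.101) and Casp4 (0.0570), and all but the call of Casp4 also ended without at least 1 other library. In all 23 genes passed, 4 higher and 19 lower. All 23 had ranges apart, as did 19.1% of all tested genes, where chance gives 10%. Of the 23, 5 passed under every alternative that tested them: S100a9, Retnlg, Serpina3g, Zbtb16 and Csf1. Nrep, Ttc22, Hpgd, Adamts5, Evpl and Cdc42ep3 were the next higher genes and did not pass, with adjusted p between 0.0548 and 0.0676.

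The same 4 members of the inflammatory list, Csf1, Ccl2, Vcam1 and Icam1, fell over all genes tested and 12 of 18 fell adjusted over the list alone (camera adjusted p = 2.64e-17, adjusted p = 0.107 with an estimated correlation). Of these 4 calls only that of Csf1 held without each library in turn, and without GQYS replicate 3 the adjusted p of Ccl2, Vcam1 and Icam1 was 0.101, 0.0958 and 0.119. Of the heat shock list 1 gene fell, Hspb8, whose call held only without WT replicate 1 among the libraries left out, and 14 of 17 adjusted over the list alone (camera adjusted p = 2.08e-17, adjusted p = 0.108 with an estimated correlation). Of the endoplasmic reticulum stress list 1 gene fell, Herpud1, from 246 ± 13.3 to 112 ± 15.4 FPKM, and 12 of 19 adjusted over the list alone (camera adjusted p = 3.38e-13, adjusted p = 0.0915 with an estimated correlation). Of the glucocorticoid list Zbtb16 and Tsc22d3, also known as GILZ, fell, the first without each library in turn as well and the second not without 7 of them (adjusted p = 0.293 without GQYS replicate 3), and 7 of 17 adjusted over the list alone (camera adjusted p = 2.30e-11, adjusted p = 0.0915 with an estimated correlation). The tubular injury list had Vcam1 as its 1 gene past the threshold, a call lost without any 1 IgAN or GQYS library, and 10 of 21 adjusted over the list alone (camera adjusted p = 2.30e-11, adjusted p = 0.244 with an estimated correlation). The matrix list had 0 and 7 of 28 (camera adjusted p = 5.16e-10, adjusted p = 0.293 with an estimated correlation). Without IgAN replicate 1 the median log2 change of the matrix list went from -0.41 to -0.18 and that of the injury list from -0.63 to -0.37, with both calls kept. Socs3 was the 1 immediate-early gene that fell, with 7 of 24 adjusted over the list alone (camera adjusted p = 2.18e-10, adjusted p = 0.350 with an estimated correlation). The cholesterol biosynthesis, macrophage, glycolysis, oxidative stress and mesangial lists also passed downward by camera (adjusted p = 1.08e-05, 0.00425, 0.00425, 0.00433 and 0.0135), and the endothelial and podocyte lists passed upward (0.00519 and 0.0334), all with no member past the threshold over all genes tested. None of these 7 held with an estimated correlation (adjusted p = 0.357, 0.621, 0.507, 0.245, 0.164, 0.293 and 0.590). Without IgAN replicate 1 the macrophage, endothelial and podocyte calls ended (adjusted p = 0.105, 0.0637 and 0.306), and without IgAN replicate 3 the mesangial call did (0.143). The podocyte call also ended without GQYS replicate 2 and IgAN replicate 2 in turn (0.241 and 0.0744). Fry's directional test passed for the inflammatory, endoplasmic reticulum stress, heat shock, glucocorticoid and mesangial lists (adjusted p = 0.0144, 0.0144, 0.0198, 0.0144 and 0.0198). Usp2, a clock-controlled gene, fell from 17.7 ± 1.80 to 10.2 ± 0.870 FPKM, a call that held only without WT replicate 1 among the libraries left out (adjusted p = 0.293 without GQYS replicate 3). The count of genes was 6 without GQYS replicate 3, 9 without IgAN replicate 1, 10 without IgAN replicate 2, 11 and 12 without GQYS replicates 1 and 2, 54 without WT replicate 1 and 63 without WT and IgAN replicate 1 together. It was 404 with quality weights, 447 with the mitochondrial covariate, and under quantile normalization 1 gene was higher and 15 lower.

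**Figure D2:**
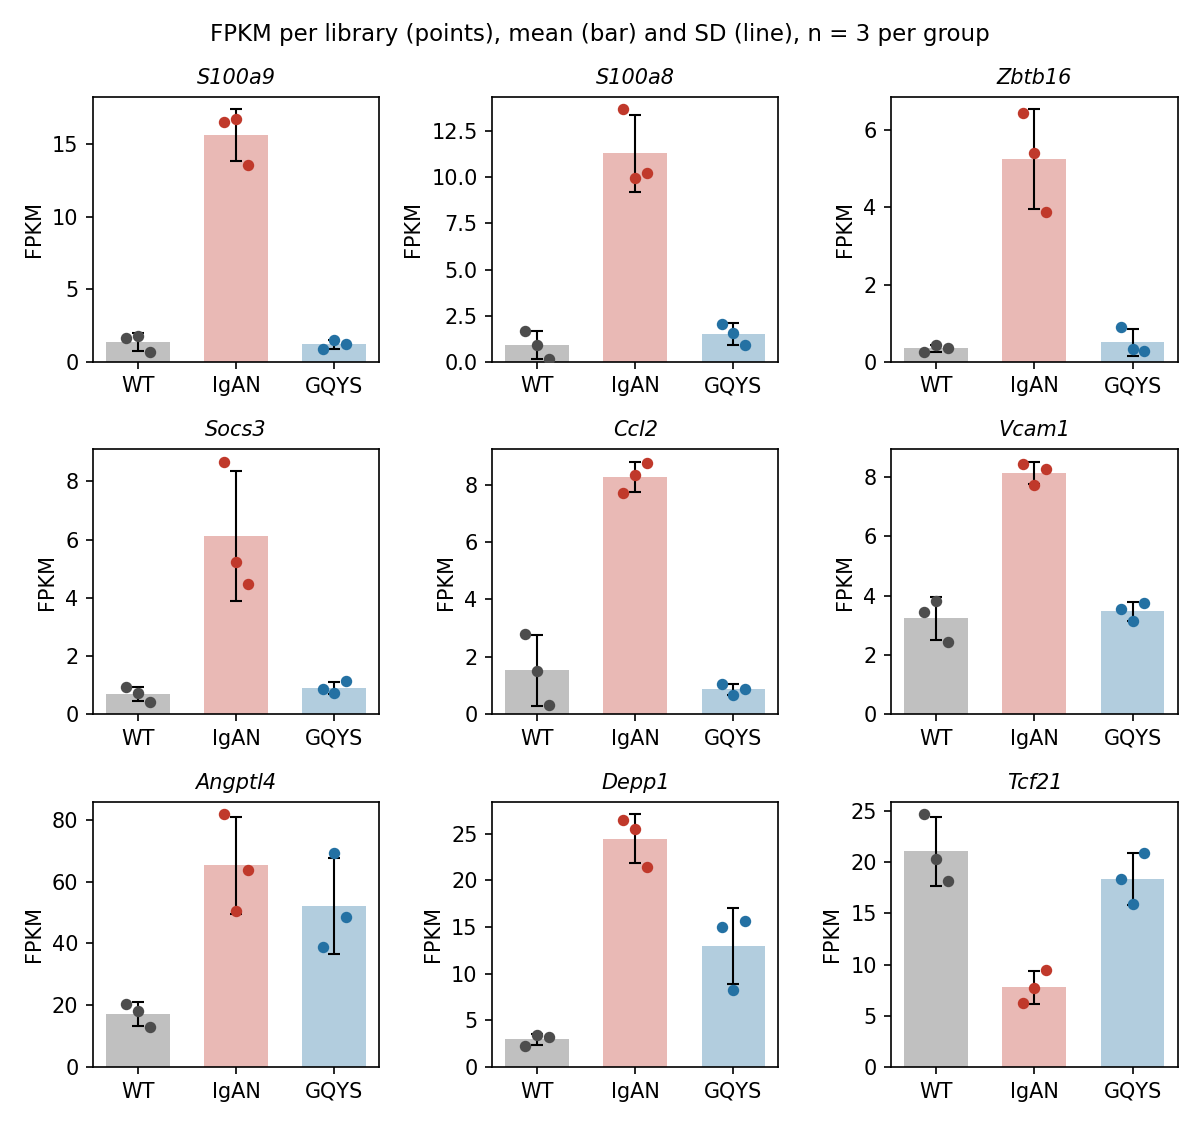
FPKM of 9 genes in the 3 groups, with points for libraries, bars for group means and lines for the SD (n = 3). S100a9 stood at 15.6 FPKM in IgAN against 1.37 in WT and 1.22 in GQYS, while Angptl4 was at 52.2 FPKM in GQYS against 17.1 in WT.

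Genes that differed in IgAN were compared with their values after the granules. Of the 41 genes past the threshold in IgAN against WT, 17 also passed in GQYS against IgAN with the opposite sign, 15 of them higher and then lower and 2, Tcf21 and Nap1l5, lower and then higher. The 10 with the smallest p in both comparisons were Retnlg, S100a9, Serpina3g, Zbtb16, Csf1, Casp4, Socs3, S100a8, Herpud1 and Cebpd. All 41 had the opposite sign, 38 of them at an unadjusted p below 0.05. Independent lists of these sizes would share 0.0593 genes of opposite sign, and simulated unchanged groups sharing the IgAN libraries gave 0. Only 1 of 100 draws had any gene past the threshold in IgAN against WT and only 3 did in GQYS against IgAN, so this 0 sets no expectation. Among the 41 genes with the smallest p of each draw, 35 ± 11 had the opposite sign and 12 ± 14 had it at an unadjusted p below 0.05 (SD of 100 draws), and 51 and 11 draws reached the 41 and the 38. The shared libraries alone can therefore give such signs. Depp1 and Angptl4 were among the genes that did not pass in the second comparison (adjusted p = 0.167 and 0.740). Across genes, which are not independent replicates, the 2 sets of fold changes had a Pearson r of -0.75, while the simulation gave -0.48 ± 0.39 (SD of 100 draws). The covariance was -0.0443 against a simulated -0.0163, and the difference of -0.0280 was close to the SD of the draws, 0.0214. The IgAN libraries enter both comparisons and are too few to be divided, so part of the excess can come from sharing them. The count was 29 without WT replicate 1, and also without WT and IgAN replicate 1 together, and 10 without WT replicate 2. Without IgAN replicates 1, 2 and 3 it was 8, 9 and 11, and without GQYS replicates 1, 2 and 3 it was 11, 8 and 6.

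**Figure D3:**
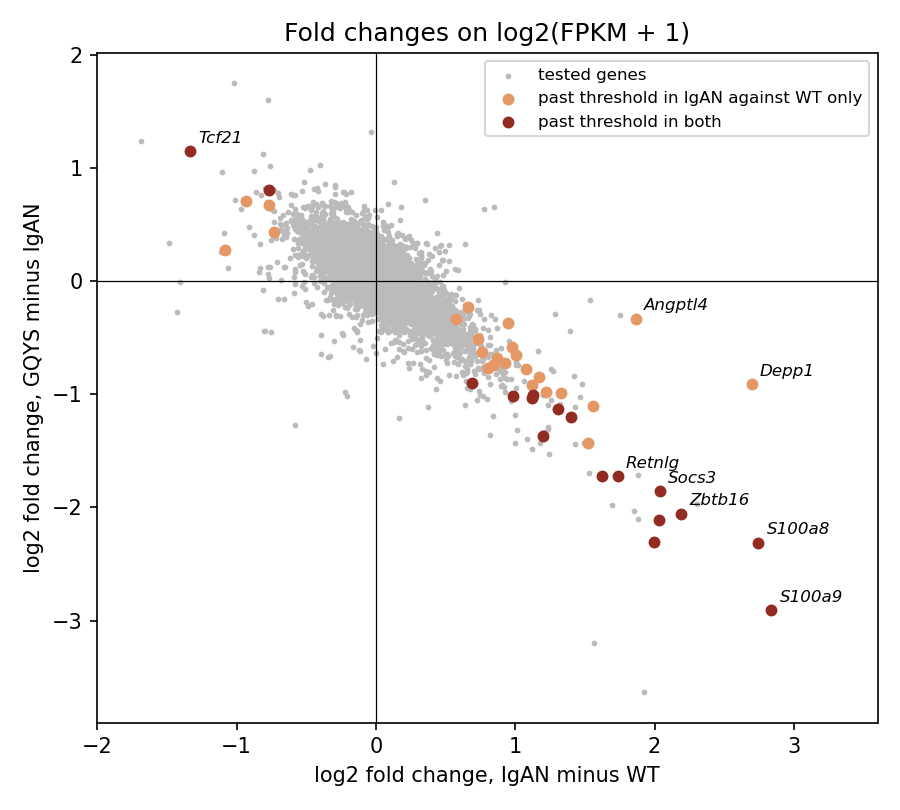
Log2 fold changes of the tested genes in IgAN against WT (x axis) and GQYS against IgAN (y axis), 1 point per gene, with genes past the threshold in both in dark red and in the first only in orange. The 17 dark red genes lie at lower right or upper left, and Depp1 and Angptl4 lie at the right nearer the horizontal axis.

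Comparison of the GQYS group with WT asked which differences remained. Depp1 was between 8.28 and 15.6 FPKM in the GQYS libraries against 2.95 ± 0.627 in WT (SD, n = 3; limma log2 change 1.79, adjusted p = 0.126) and Angptl4 at 52.2 ± 15.5 against 17.1 ± 3.75 (1.54, adjusted p = 0.317). A4galt, Eps8l1, Cbx2, Ipmk, Rhebl1, Hmcn2 and Med18 were the next higher genes, and Lonrf3, Insl6, Cbr2, Id3, Nudt19, Ccl28, Gpc1, Tchhl1, Zkscan3 and Dynlt1b the lower ones, all short of the threshold. Dbp, a clock output transcription factor, was at 5.91 ± 1.73 against 1.82 ± 0.627 FPKM (adjusted p = 0.481). By limma 0 genes passed, 515 had an unadjusted p below 0.05, and voom on the recovered reads also gave 0. FPKM ranges were apart for 9.74% of genes, where chance gives 10%.

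The 15 tested endothelial genes all had positive changes in GQYS against WT, with a median of 0.30, and 1, Plat, tissue plasminogen activator, passed adjusted over the list alone (camera adjusted p = 9.62e-09, adjusted p = 0.175 with an estimated correlation). Plat was at 25.9 ± 0.653 FPKM in GQYS, 19.0 ± 1.48 in WT and, higher still, 30.7 ± 3.79 in IgAN (SD, n = 3). It had also passed in IgAN against WT (limma adjusted p = 0.0447), a call that ended without 7 of the libraries in turn. The fatty acid oxidation list had 0 genes past the threshold and 3 of 36 adjusted over the list alone (camera adjusted p = 0.000401, adjusted p = 0.840 with an estimated correlation). The podocyte, interferon, endoplasmic reticulum stress and ribosomal protein lists passed upward by camera (adjusted p = 0.0168, 0.0142, 0.00597 and 0.00448) and the immediate-early, cholesterol biosynthesis, thick limb, macrophage and sex-biased lists downward (0.00182, 0.00119, 0.0233, 0.0345 and 0.0345), with 0 members past the threshold over all genes tested and, apart from Cldn16 of the thick limb list, 0 adjusted over the list alone. With an estimated correlation their smallest adjusted p was 0.840, so 11 of 32 lists passed with the preset correlation and 0 with an estimated one. Apart from the endothelial call, each of these calls ended without at least 1 library. Without WT replicate 2 the podocyte, endoplasmic reticulum stress, ribosomal protein, thick limb, macrophage and sex-biased calls ended (adjusted p = 0.312, 0.312, 0.779, 0.217, 0.986 and 0.429), without WT replicate 3 the interferon, ribosomal protein and cholesterol calls (0.928, 0.878 and 0.110), and without WT replicate 1 the fatty acid oxidation, podocyte, thick limb and macrophage calls (0.0622, 0.0782, 0.0620 and 0.608). Without GQYS replicate 1 the interferon, endoplasmic reticulum stress and ribosomal protein calls ended (0.145, 0.257 and 0.329), without GQYS replicate 2 the podocyte, cholesterol, thick limb, macrophage and sex-biased calls (0.275, 0.0531, 0.0531, 0.395 and 0.0547), and without GQYS replicate 3 the sex-biased call (0.164). Without WT replicate 1 the immediate-early list turned from a median of -0.20 to 0.10 and no longer passed. With library quality weights 53 genes passed, and without GQYS replicate 2 1 gene and 6 lists did.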

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

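Voom, the fit without WT and IgAN replicate 1, and the mitochondrial covariate were chosen after seeing the data. With 3 libraries per group the self-test, whose noise was independent across genes and libraries, recovered 14.9% of genes changed 1.5-fold in IgAN against WT. In that setting small changes were mostly out of reach. Of the 64 gene calls of the first 2 comparisons none changed direction, 49 ended under at least 1 alternative, 48 of them without at least 1 library, and 15 never ended. By comparison 31 of 41 calls in IgAN against WT and 18 of 23 in GQYS against IgAN ended. Among the genes named there, those ended most often were Igfbp3, Hspb8, Usp2 and Nap1l5 in GQYS against IgAN (17, 15, 15 and 14 alternatives) and Ccdc68 and Nap1l5 in IgAN against WT (16 and 12). Socs3 in GQYS against IgAN ended only without a filter (adjusted p = 0.0563). The number of genes changed IgAN against WT (41) was 24 with the filter at FPKM 5, 21 without a filter, 11 with only the 2 groups compared, 25 with libraries rescaled to equal sums, 282 at an unadjusted p with at least 1.5-fold, 655 with quality weights, 815 with the mitochondrial covariate and 58 without WT and IgAN replicate 1. The 655 and the 815 each included all 41, and the 58 included 30. The number of genes changed GQYS against IgAN (23) was 14, 13, 43, 15 (pseudocount 0.1), 296, 404, 447 and 63 under the filter, no filter, 2 groups, that pseudocount, the unadjusted rule, weights, covariate and the fit without both libraries. Voom gave 30 and 17, sharing 28 and 14. The number of genes changed GQYS against WT (0) was 53 with weights and 75 by the unadjusted rule. The number of genes changed in IgAN and moved back with GQYS (17) was 11, 10, 9, 205, 272 and 29 under the filter, no filter, 2 groups, weights, covariate and without both libraries. The correlation of IgAN minus WT with GQYS minus IgAN fold changes (-0.75) was -0.61 without both libraries and otherwise moved by less than its jackknife error. List counts went to 0, 0 and 0 with an estimated correlation. The cause of these shifts was not tested, and some of the fits also held fewer libraries or genes.

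Leaving out 1 library at a time gave 14 to 65 genes for IgAN against WT, 6 to 54 for GQYS against IgAN, 0 to 1 for GQYS against WT, 6 to 29 reversed genes, and 10 to 15, 14 to 15 and 6 to 11 lists. The immediate-early list in GQYS against WT turned from a median of -0.20 to 0.0266 with quality weights and 0.0980 without WT and IgAN replicate 1, with a range of -0.434 to 0.0980 over single libraries left out, the highest without WT replicate 1. The camera direction of the mitochondrially encoded list in IgAN against WT turned, with medians of 0.0454 with weights and -0.00715 with the covariate, and a range of -0.564 to -0.0179 over single libraries left out, the last without WT replicate 1. The covariate is the read share of the genes of this list, so it takes out their change by construction and tests nothing for them. The separation of the groups stayed short of the threshold, with p between 0.0714 and 0.243. Itgam kept its direction, and the block, weights and prior settings were not run for it because its test is a permutation of means. The replicate block gave 68 genes for IgAN against WT. Of 9 same-number pairs 6 correlated above 0.1, and 4 libraries correlated best with their own number. Same-number pairs ranged from -0.364 to 0.581 and other pairs from -0.629 to 0.526. These are replicate numbers, which are not the numbers in the library names, such as C2, M2 and H3 for replicate 1. By library name, C2 with M2 and C5 with M5 correlated at 0.581 and 0.526. C3 with H3 and M6 with H6 correlated at -0.208 and -0.100. The labels do not say that either numbering pairs the samples, so pairing is left open and the replicate block does not test it.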

Other observations

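All tests of explanations here were chosen after the values were seen; only the counts over other splits were planned before. Several cell-type lists lay below the expression filter and were read from the fit on 23797 genes without it. Of 13 neutrophil genes, 3 rose in IgAN against WT over all genes tested (S100a8, S100a9, Retnlg), 8 adjusted over the list alone, and 8 were higher in every IgAN library than in every WT library. Csf3r, the G-CSF receptor, was at 1.01 ± 0.205 FPKM in IgAN against 0.208 ± 0.136 in WT and 0.238 ± 0.0764 in GQYS (SD, n = 3). The neutrophil list passed camera with an estimated correlation as well, with camera adjusted p of 0.0463 for IgAN against WT and 0.0371 for GQYS against IgAN. For GQYS against WT it lay at 0.951. These values come only from the fit without a filter and were not repeated without single libraries. Only 4 genes of the list had passed the filter of the main test, so it was not tested there. Of 11 B and plasma cell genes, 0 fell over all genes tested, and adjusted over the list alone 4 fell and 1 rose. Jchain, the joining chain of polymeric IgA and IgM, was at 3.21 ± 1.81 FPKM in IgAN, 13.4 ± 9.58 in WT and 8.47 ± 2.42 in GQYS, and the list's camera adjusted p was 0.000123, with 0.240 under an estimated correlation. In GQYS against IgAN it passed upward at 0.00418, with 0.335 under an estimated correlation. For IgAN against WT the T and NK cell, adipose, adrenal, muscle, lymphoid and urothelial lists had adjusted p of 0.975, 0.670, 0.865, 0.539, 0.792 and 0.761 with an estimated correlation, and of these the adipose list passed downward at the preset one (adjusted p = 0.0116). In GQYS against WT the adipose, lymphoid and urothelial lists passed downward by camera (adjusted p = 0.00203, 0.00433 and 0.00226; 0.816 for each with an estimated correlation), and WT replicate 3 held the highest Cfd and Upk1a. The erythroid, proximal tubule, complement and cell cycle lists did not pass camera in any comparison, with adjusted p in IgAN against WT of 0.416, 0.416, 0.172 and 0.848.

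S100a8, S100a9 and Retnlg were higher in IgAN than in WT. More blood left in the kidneys argues poorly for this, because the highest log2 change plus 2 SE among 4 globin genes and Alas2 was 0.83, below the smallest rise of the 3 genes, 1.74. Scaling does not account for it either, since the largest adjusted p over 3 other scalings was 0.00631. More neutrophils in the sampled tissue or in its blood remain a candidate explanation. Of the 10 other neutrophil genes, 5 were higher in every IgAN than in every WT library and the rest were not. Itgam, a myeloid gene, had a lower mean in IgAN than in WT (0.289 against 0.495 FPKM), but it is the knock-in locus. Whether the knock-in, the disease or handling of the group brought more neutrophils was not tested.

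Of 17 glucocorticoid response genes, 2 rose in IgAN against WT and 2 fell in GQYS against IgAN over all genes tested, and the list's camera calls did not hold with an estimated correlation (adjusted p = 0.122 and 0.0915). Without WT and IgAN replicate 1 the list's median log2 change in IgAN against WT was 0.49, against 0.65 with them (camera adjusted p = 9.95e-09 without), so these libraries may carry part of it. A clock index (Dbp, Nr1d1, Nr1d2, Tef and Per3 minus Bmal1, Npas2, Clock, Nfil3 and Cry1; members chosen after their values were seen, without Hlf) was 1.06 higher in GQYS than in IgAN (exact permutation p = 0.1) and differed by 0.0042 between IgAN and WT (p = 1), but genes picked this way test nothing. Of the 17 tested genes of the circadian list fixed beforehand, Usp2 fell in GQYS against IgAN over all genes tested, a call lost without 8 of the 9 libraries in turn (adjusted p = 0.293 without GQYS replicate 3), and 2 rose and 5 fell adjusted over the list alone. Camera, which looks for a shift in 1 direction, did not pass for it in GQYS against IgAN (adjusted p = 0.181, 0.621 with an estimated correlation) or IgAN against WT (0.0762 and 0.602), while fry for changes in either direction did in both (adjusted p = 0.00190 and 0.0179). That fry test also passed in both for other lists, such as the complement (0.0188 and 0.0232) and inflammatory lists (0.000929 and 0.000310). It therefore does not set the circadian list apart. Time of collection is not in the labels and cannot be told apart from group.

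Tubular injury genes were highest in IgAN replicate 1, with Havcr1 at 43.8 FPKM. Urothelium carried over is argued against by its summed uroplakin level of 0.636 FPKM, below the median of the other 8 libraries, 2.80. A state shared with WT replicate 1, the other library apart on the first component, was looked for in the injury level alone. That of WT replicate 1 differed by -0.0716 on the log2 scale from the other WT libraries, while IgAN replicate 1 exceeded its group by 1.03. This argues against a raised injury level in both, but not against another shared state. Across genes, the deviations of these libraries from their group means had the highest correlation of the same-number pairs, 0.581. The bound for that test was reworded after its value was seen, since it had not covered a value below the range. More severe disease in that animal was not tested.

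The 6 libraries of a comparison divide into 3 and 3 in 10 ways, too few for a share under 0.05, and every count of splits here includes the real grouping. For IgAN against WT 2 splits gave at least the 41 genes; the other, WT 1 with IgAN 1 and IgAN 3, gave 605, which points to a structure of the samples other than group. For GQYS against IgAN 1 split, the real one, gave 23, and the highest other gave 0. For GQYS against WT all 10 gave 0. For lists, 6, 4 and 2 splits gave as many as the real 13, 14 and 11, with highest others of 16, 15 and 13. For the reversal, 1 of 100 assignments of the 9 libraries, the real one, gave as many as 17 genes and the highest other gave 0. None of the other 99 had a gene past the threshold in both comparisons. Only 2 had any in the first, at most 19 genes, and 6 in the second, at most 1655. Their counts therefore had little room to differ from 0, so the rank of the real assignment does not exclude chance assignment for that count. Nor does it exclude a cause other than the knock-in that the 3 IgAN libraries share.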
